A study of Rattus norvegicus with 6 samples.

How the data were processed

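Small RNA sequencing reads that align to tRNAs were compared between 3 libraries titled as control and 3 titled as experimental, made from rat muscle. The titles alone gave the groups, since the design text and a skin characteristic in the labels describe another experiment in mouse skin. Per the labels, the animals were 6 to 8 weeks old and 1 inbred strain was named for all 6 samples. Nothing says whether the 3 libraries of a group came from separate animals, so p-values measure only the spread between these libraries, which may be technical.

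Per the file headers and values, the authors collapsed reads to distinct sequences and aligned them to mature tRNAs with CCA added and to precursor tRNAs, and deposited a read count per sequence and library. The deposited table held 77567 distinct sequences of 14 to 40 nt in 123568 alignments to 225 mature and 379 precursor tRNAs, with at most 1 mismatch per alignment and a fragment type per alignment. The aligner and its version were not given in the sources used here. The submitters' processing notes name mm9, but the tRNA set reaches chromosome 20 and position 266305512 of chromosome 2, so the positions are not of that mouse build. Coordinates are given as in the files, counted from 1, on a build not given in the sources used here. The deposited counts are raw, and for every sequence they equalled the number in the read names of the library's own alignment file. Reads with more than 1 difference from the reference are not in the table, which lowers counts where the animals differ from it. The tRNA-aligned totals ranged from 316990 to 1927269 reads. Total library depth was not analysed here.

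A sequence was counted once however many tRNAs it matched, and 21250 sequences matched more than 1. For anticodon sums, a sequence on several anticodons (8407 sequences) was split equally among them, with nuclear and mitochondrial tRNAs apart, and sums were rounded. Sequences were kept with at least 10 counts' worth of CPM in the median library in 3 libraries and at least 15 counts in all. Trimmed mean of M values factors (log ratio trim 0.3, sum trim 0.05) scaled the libraries, and normalised CPM are relative to the reads of the kept features times that factor. For fragments the factors were 0.986, 1.099 and 1.194 in the control and 1.463, 0.562 and 0.939 in the experimental libraries. For anticodons they were 1.23, 0.947 and 1.24 in the control and 1.223, 0.892 and 0.635 in the experimental libraries. Groups were compared with limma 3.58.1 voom (prior count 0.5) in R 4.3.3, with no covariate, Benjamini-Hochberg adjustment and a threshold of 0.05. The plan written before the data were examined named a quasi-likelihood count test. Voom was used in its place because lines of text interleaved with the counts (1812 lines, 1.47% of the alignments) kept the table from passing an automatic check of count columns. That choice was made before any fit was run. The plan's fallback, limma on log2 values with a pseudocount of 1, is among the alternatives and was listed there after trial counts of calls under several settings had been seen.

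In the fragment comparison limma estimated an infinite prior degrees of freedom, so that all fragments shared 1 pooled spread and standard errors lay between 0.872 and 1.07. Fragments rise and fall together within a library, and such pooling treats them as separate evidence. A fit with each fragment's own spread was therefore added after the data were seen. In the anticodon comparison the prior degrees of freedom were 6.19.

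Lists fixed before the data were examined were tested with limma's camera at a preset correlation of 0.01 where at least 5 members were tested, and again with an estimated correlation and with fry. The lists were nuclear amino acid families, the fragment types of the files, mitochondrial tRNAs, tiRNA-5 of tRNAs often reported as cleaved under stress, tiRNA-5 of tRNAs often reported in circulating blood, and tRF-3 ending in CCA. A list of Leu-CAG tRF-3 had too few tested members. Shares of reads per fragment type, the mitochondrial share and the mean read length were compared with two-sided exact permutation tests, whose smallest p with 3 against 3 libraries is 0.1. Wilson intervals at 95% and floors of 3 counts over a group cover counting error only, since PCR copies are not independent molecules.

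Fragments were named by a rule set before the data were examined. It takes the 10 largest rises and the 10 largest falls with adjusted p under 0.05, at least 50 CPM in the higher group and no overlap between groups, the 8 most abundant fragments, and the most abundant member of each list. Fragments of a tRNA whose ends lie within 2 nt, with or without a mismatch, share a place. The most abundant of those that pass is named, so it may have changed less than the fragment that ranked first. Anticodons were to be named among those called, with the 5 most abundant. Positions count from 1 at the mature tRNA's 5' end, and a substitution gives the reference base, the position and the read's base.

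The fits were tested on simulated counts. In the fragment comparison (200 fragments changed), 5% of fragments changed by 1 on the log2 scale, 19.3% of those changed by 2 and 69.2% of those changed by 3 were recovered among 2040 fragments, and 3.8% of calls were false. In the anticodon comparison, among 69 anticodons of which 15 were changed, 40% of those changed by 1 and 100% of those changed by 2 or by 3 on the log2 scale were recovered, and 7.7% of calls were false. The simulated features varied independently of each other, unlike the real ones. All were drawn with 1 dispersion (0.333 for fragments and 0.182 for anticodons), so the simulation cannot test the pooling of the spread. Alternatives were other scalings and filters, a replicate block, leaving out each library, subsets of sequences, other class rules and other set tests. A planned second count test was not run. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the remaining steps.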

Results

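Small RNA libraries of rat muscle were read out as fragments of tRNAs, the short RNAs left when tRNAs are cut. There were 3 control and 3 experimental libraries. The series title concerns tRNA-derived fragments as markers of acute rejection after transplantation of a composite tissue such as a limb, and the labels do not say how the experimental samples were treated. The control libraries held 550004, 740627 and 316990 tRNA-aligned reads, and the experimental libraries held 876494, 1927269 and 1866227. The experimental libraries were deeper throughout, so rare fragments were measured more closely there.

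The types of fragment differed in the share of reads they took. The tiRNA-5, fragments that run from the 5' end of the tRNA to the anticodon, took 2.31% ± 0.270 (SD, n = 3) of tRNA-aligned reads in the control and 11.2% ± 3.16 (SD, n = 3) in the experimental libraries. Taken by position, 5' fragments that end in the anticodon loop, many of them typed as tRF-5c in the table, took 64.3% ± 7.80 in the control and 75.99% ± 10.95 in the experimental libraries, with overlap (exact permutation p = 0.2). The tRF-3a, short fragments of the 3' end, took 1.58% ± 1.08 in the control and 0.462% ± 0.264 in the experimental libraries, a difference of -1.12 percentage points that was -0.506 without control replicate 1. The tiRNA-3, which run from the anticodon to the 3' end, took 0.00804% ± 0.00383 in the control and 0.000554% ± 0.000424 in the experimental libraries. Taken by position, 3' fragments that start in the anticodon loop took 0.4047% ± 0.0135 and 0.2999% ± 0.133, with overlap (exact permutation p = 0.4). In each of these 3 types as given in the table the groups did not overlap, with the smallest p that an exact two-sided permutation test of 3 against 3 libraries can give (p = 0.1, adjusted p = 0.3), so none passed a threshold of 0.05. The tRF-5c, 5' fragments that stop before the anticodon, took 72.8% ± 3.86 and 60.0% ± 12.9 of reads (exact permutation p = 0.3), a difference of -12.9 percentage points, smaller than the spread of the experimental libraries, and of -6.61 without experimental replicate 1. Reads typed as Other took 22.1% ± 4.57 and 27.6% ± 10.6, and without experimental replicate 1 the difference turned from 5.51 to -0.154 percentage points.

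**Figure D1:**
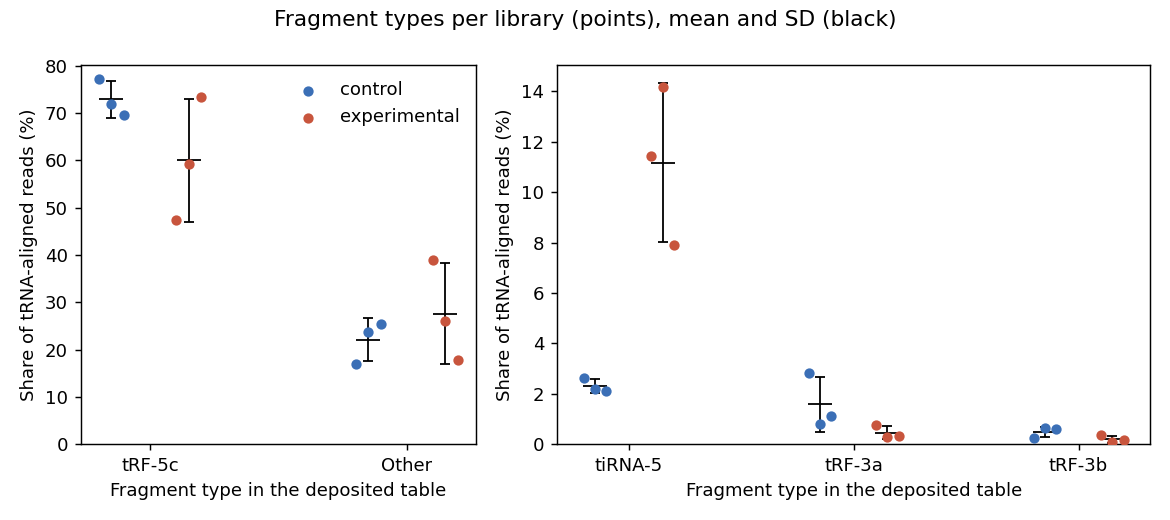
Share of tRNA-aligned reads (%, y axis) by fragment type of the deposited table (x axis), with points for the 3 control (blue) and 3 experimental (red) libraries and black marks for the mean and SD. The tiRNA-5 lay between 2.12% and 2.62% in the control and between 7.89% and 14.2% in the experimental libraries.

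Reads of glycine tRNAs made up 77.5% ± 3.88 of the control and 74.8% ± 9.19 of the experimental reads. Among 5' fragments of Gly-GCC and Gly-CCC, those ending at position 31 took 53.6% ± 7.40 in the control and 31.3% ± 12.7 in the experimental libraries, and those ending at position 30 took 21.6% ± 9.05 and 6.93% ± 3.47. Ends at position 32 took 15.2% ± 3.09 and 32.0% ± 3.58, ends at position 33 took 1.53% ± 0.671 and 9.32% ± 2.98, and ends at position 34 took 1.20% ± 0.956 and 10.01% ± 6.32. The groups did not overlap at any of these 5 positions (exact permutation p = 0.1 each, the smallest possible, not adjusted, among 14 positions). Over all of these fragments the mean end lay at -1.91 ± 0.178 nt from the first anticodon base in the control and at -1.26 ± 0.339 nt in the experimental libraries, without overlap (exact permutation p = 0.1). The mean length of all tRNA-aligned reads was 29.6 ± 0.420 nt in the control and 30.7 ± 0.926 nt in the experimental libraries (exact permutation p = 0.1), a difference of 1.09 nt that was 0.582 nt without experimental replicate 2. The 5' fragments of glutamic acid tRNAs went the other way. Their mean end lay at 1.40 ± 1.16 nt from the first anticodon base in the control and at -1.17 ± 0.540 nt in the experimental libraries, without overlap (exact permutation p = 0.1). For 5' fragments of histidine and lysine tRNAs and of mt-Ser the groups overlapped. Their mean ends lay 0.222, 0.544 and 0.177 nt further 3' in the experimental libraries, the same direction as for glycine.

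**Figure D2:**
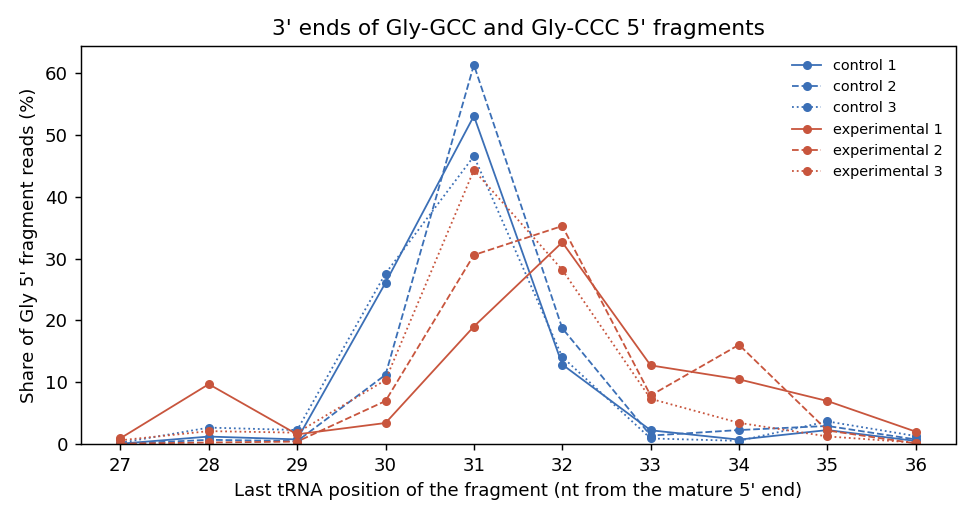
Share of Gly-GCC and Gly-CCC 5' fragment reads (%, y axis) by the last tRNA position of the fragment (nt from the mature 5' end, x axis), 1 line per library, control in blue and experimental in red. At position 32 the experimental libraries held 28.2% to 35.3% and the control libraries 12.9% to 18.8%.

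Mitochondrial tRNAs, which serve the organelle abundant in muscle, gave 13.003% ± 6.45 (SD, n = 3) of control and 8.78% ± 6.58 (SD, n = 3) of experimental reads. The libraries ranged from 5.61% to 17.5% in the control and from 2.46% to 15.6% in the experimental group. The difference was within the spread of the libraries (exact two-sided permutation p = 0.5). It stood at -4.22 percentage points, at -1.06 without experimental replicate 2 and at -7.92 without control replicate 1.

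Single fragments differed in both directions, and most of those named for their rise or fall were mitochondrial. Of 2226 fragments tested, 416 were higher and 170 lower in the experimental libraries (limma voom, adjusted p under 0.05). With each fragment's own spread in place of 1 spread pooled over all fragments, 15 were higher and 8 lower, and 590 had an unadjusted p under 0.05, so the count rests on the pooling. The groups did not overlap in 40.7% of the fragments tested, where chance gives 10% for a single fragment. Fragments vary together within a library, so a random split can give a share far from 10%. That share was not counted for other splits, so chance is not excluded. Of the 586 calls, 194 were mitochondrial, as were 787 of the 2226 fragments tested, so calls were not enriched in them. Those higher made up 18.69% of the fragments tested, and 6.96% without control replicate 3. Without control replicate 1 the counts were 668 higher and 283 lower, and without experimental replicate 3 there were 109 lower. The median log2 fold change was 0.21 with the scaling used, 0.01 with median-of-ratios factors and -0.07 with library totals.

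Among nuclear fragments, the naming rule took a fragment beyond the 3' end of Thr-AGT on chromosome 10, positions 75 to 111, and 3 long 5' fragments. The first had no reads in the control libraries and 212 ± 138 CPM in the experimental ones. It was at least 116-fold higher against a floor of 3 counts over the control group (73.2-fold without experimental replicate 2). Reads with more than 1 difference from the reference were not counted, so control reads that differ more from it there would be missed. The 5' fragments stand for rarer sequences with a mismatch and nearly the same ends, which rose more, by 7.34, 6.30 and 7.05 on the fitted log2 scale for Lys-CTT of chromosomes 2 and 6 and for Gly-GCC. The Lys-CTT fragment of positions 1 to 34 from the gene on chromosome 2 (198567936 to 198568008) rose from 1805 ± 980 to 24140 ± 25151 normalised CPM (SD, n = 3 each), a log2 fold change of 3.40 ± 0.88 (SE, limma voom adjusted p = 0.00138). Its counterpart from the gene on chromosome 6 (93417550 to 93417622) rose from 297 ± 178 to 13747 ± 18725 CPM, by 4.67 on the log2 scale. Experimental replicate 2 held 35366 CPM of it and the other experimental libraries 2664 and 3211 CPM, and without that replicate the log2 fold change was 3.55. The Gly-GCC fragment of positions 1 to 34 rose from 6422 ± 5827 to 68700 ± 71574 CPM, by 3.28 on the log2 scale (limma voom adjusted p = 0.00213). Without control replicate 3, the Gly-GCC fragment (adjusted p = 0.12) and the Lys-CTT fragment of chromosome 2 (adjusted p = 0.098) were no longer called by limma voom, at log2 fold changes of 2.34 and 2.51. Without experimental replicate 3 these were 4.02 and 4.04. Experimental replicate 2 carried the means of both, with 151031 CPM of the Gly-GCC fragment against 33786 and 21282 CPM, and 53165 CPM of the Lys-CTT fragment against 10476 and 8778 CPM. That replicate had the lowest scaling factor (0.562), which raised its CPM. Without experimental replicate 2 the log2 fold changes were 2.51 and 2.64. With each fragment's own spread none of the 3 was called (adjusted p = 0.141 and 0.138 for Lys-CTT of chromosomes 2 and 6 and 0.175 for Gly-GCC, limma voom), while the Thr-AGT fragment was (adjusted p = 0.0375).

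**Figure D3:**
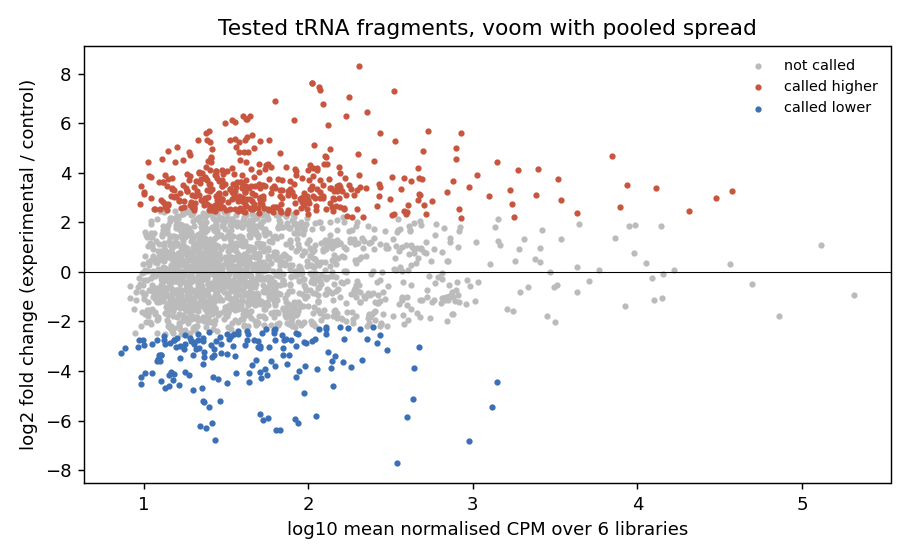
log2 fold change (experimental over control, y axis) against log10 mean normalised CPM over the 6 libraries (x axis) for the 2226 tested fragments, with fragments called higher in red, lower in blue and not called in grey. With the spread pooled over fragments 416 were called higher and 170 lower; with each fragment's own spread 15 and 8 were.

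The most abundant fragment, positions 1 to 31 of Gly-CCC and Gly-GCC, stood at 255125 ± 63441 CPM in the control and 159045 ± 94908 CPM in the experimental libraries and was not called (limma voom adjusted p = 0.459). Experimental replicate 1 held 49885 CPM of it and the other experimental libraries 205224 and 222027 CPM. The log2 fold change was -0.926, and it was -0.445 without experimental replicate 1 and -1.54 without control replicate 3. Also not called were the Gly-GCC fragment of positions 1 to 31 from chromosome 13 (log2 fold change 0.32), the Gly-CCC and Gly-GCC fragment of positions 1 to 28 (0.36), mt-Ser-GCT 1 to 19 (-1.13), Glu-CTC 1 to 39 (-1.39) and Glu-CTC 1 to 33 (1.36). Glu-CTC 1 to 39 was called lower without experimental replicate 1 (-2.43, limma voom adjusted p = 0.0134) and stood at -0.847 without experimental replicate 3. With 1 library left out, mt-Ser-GCT 1 to 19 lay between -1.84 and -0.575 and Glu-CTC 1 to 33 between 0.767 and 1.78.

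The mitochondrial calls went in both directions within single tRNAs, and many lay on reads that differ from the reference. The fragment of positions 49 to 71 of mt-Cys-GCA had no control reads and 408 ± 374 CPM in the experimental libraries, at least 224-fold higher (107-fold without experimental replicate 1). Fragments 38 to 55 and 38 to 52 of that tRNA were at least 46.3-fold and 45.7-fold higher. All 3 match the reference over position 51, where 94.1% to 100% of control reads carry T51C, and the sum over mt-Cys-GCA had a log2 fold change of -0.01. Beyond the 3' end of that tRNA, the fragment 80 to 94 rose from 32.4 ± 19.6 to 304 ± 216 CPM (limma voom adjusted p = 0.00519), and it was not called without control replicate 3 (adjusted p = 0.0911). Like the reads 81 to 101 and 86 to 101 named below, it also aligns to the mt-Asn-GTT precursor. Reads that lie beyond the 3' end of mt-Val-TAC, from position 69 to position 89, rose from 3.88 ± 3.87 to 661 ± 321 CPM when they matched the reference, and fell from 2679 ± 982 to 122 ± 38.1 CPM when they carried T74C. The same reads ending at position 93 were at least 68.5-fold higher without the substitution, and fell by 3.88 on the log2 scale with it. The mt-Pro-TGG fragment 1 to 25 with A16G fell by 5.80 on the log2 scale, and the mt-Tyr-GTA fragment 47 to 69 with C53G fell by 4.87. The other falls named by the rule were reads 81 to 101 and 86 to 101 beyond the 3' end of mt-Cys-GCA with T101A, mt-His-GTG 26 to 54 with A54C, mt-Val-TAC 35 to 70 with C70A, reads beyond mt-Pro-TGG with G81C, and mt-Thr-TGT 39 to 70. The last matched the reference and fell from 60.0 ± 12.2 to 4.29 ± 4.33 CPM. With each fragment's own spread most of the mitochondrial fragments named here were no longer called (limma voom adjusted p from 0.0527 to 0.128). The exceptions were mt-Val-TAC 69 to 89 with T74C, mt-Val-TAC 69 to 93 without it, and mt-Cys-GCA 81 to 101 with T101A. Of the 586 calls, 46 lay on sequences over a position whose mismatch share, pooled over each group, differed by at least 50 percentage points. That search left out 2 bases at each read end and positions with under 30 reads in a group. The named falls with T101A, A54C, C70A and G81C carry their substitution at such a read end and are not among the 46, which is thus a lower limit.

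**Figure D4:**
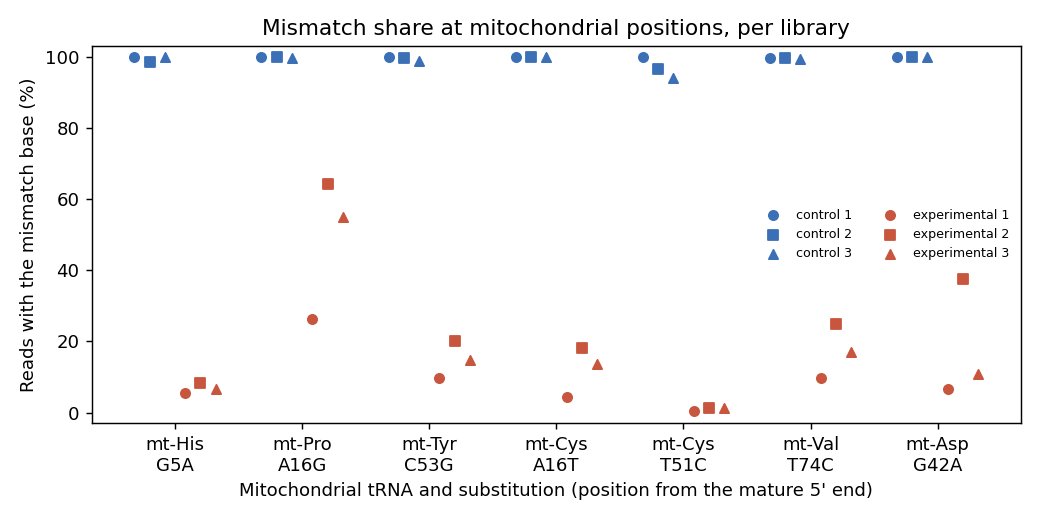
Share of reads with the mismatch base (%, y axis) at 7 mitochondrial positions (x axis, substitution with its position from the mature 5' end), with 1 point per library, control in blue and experimental in red. Control libraries lay between 94.1% and 100% and experimental libraries between 0.5% and 64.1%.

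Summed by anticodon, no tRNA passed the threshold. Of 69 anticodon sums, 0 were called by limma voom, 6 had an unadjusted p under 0.05, and limma trend called 2, Lys-CTT and Thr-AGT, both higher. Lys-CTT is among the 5 most abundant sums, and Thr-AGT is named after its values were seen. Lys-CTT stood at 10400 ± 2932 CPM in the control and 72924 ± 33971 CPM in the experimental libraries (log2 fold change 2.77 ± 0.63 SE, limma voom adjusted p = 0.0532). It passed the threshold with library totals (adjusted p = 0.0353, limma voom here and below), with factors from the fragments (0.00327), with mature tRNAs only (0.00968), and without control replicate 2 (0.044) or experimental replicate 1 (0.000366). It did not pass without control replicate 1 (0.0544), control replicate 3 (0.385), experimental replicate 2 (0.181) or experimental replicate 3 (0.204). Thr-AGT had the same adjusted p (0.0532, limma voom) with a log2 fold change of 1.69, which turned to -0.455 when only mature tRNAs were counted. It was called without control replicate 1 (adjusted p = 0.0233). Val-CAC, also named after its values were seen, was called with sequences of 1 anticodon only (2.98 on the log2 scale, adjusted p = 0.00496). The other 4 most abundant sums were Gly-GCC with 397762 ± 65293 and 591077 ± 218754 CPM, Gly-CCC with 292588 ± 55022 and 305274 ± 168193 CPM, Glu-CTC with 30801 ± 415 and 59791 ± 10339 CPM, and mt-Ser-GCT with 38837 ± 22851 and 21412 ± 14818 CPM. These CPM depend on the scaling factors and are not shares of reads. Experimental replicate 3 had the lowest factor (0.635), with 797044 CPM of Gly-GCC and 491296 CPM of Gly-CCC. Gly-GCC was called higher without experimental replicate 1 (0.855 on the log2 scale, limma voom adjusted p = 0.00668) and stood at 0.492 with all libraries. The mt-Ser-GCT sum stood at -1.02, and between -1.65 and -0.209 with 1 library left out.

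The lists fixed in advance were led by the tiRNA-5. Of 150 tiRNA-5 tested, 124 were higher and 0 lower (adjusted over the list alone, 134 and 4), with a median log2 fold change of 3.28. Of 141 tiRNA-5 from tRNAs often reported as cleaved under stress, 123 were higher and 0 lower (adjusted over the list alone, 94.3% of the list higher and 0 lower). Of 139 from tRNAs often reported in circulating blood, nearly the same fragments, 122 were higher and 0 lower (adjusted over the list alone, 132 and 0). The most abundant member of these lists, Gly-GCC 1 to 33, rose from 7653 ± 4703 to 52884 ± 13192 CPM (limma voom adjusted p = 0.00587) and was not called without control replicate 3 (adjusted p = 0.178) or with its own spread (adjusted p = 0.0925). The counts of these lists rest on the pooled spread, since only 15 fragments of any kind were called higher with each fragment's own. Sequences of 1 tRNA that differ by a mismatch also count as separate members, so members are not independent evidence. Of all 586 calls 391 had 1 mismatch, and exact matches alone gave 101 higher and 91 lower of 1037 tested. Lists of exact matches alone were not counted. Of 173 lysine fragments, 85 were higher and 1 lower. Of 825 glycine fragments, 199 were higher and 8 lower. Of 57 histidine fragments, 16 were higher and 3 lower.

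Among the lists in the other direction, 10 of 76 tRF-3 ending in CCA were lower and 0 higher, as were 6 of 62 tRF-3a and 4 of 23 tRF-3b. The share of 3' fragment reads with the whole CCA end was also lower in the experimental libraries (64.5% ± 10.8 against 78.6% ± 3.82, exact permutation p = 0.1). Whether the 2 are linked was not tested. Of 21 glutamine fragments, 10 were lower and 0 higher, and of 17 leucine fragments 1 was lower. Of 787 mitochondrial fragments, 135 were lower and 59 higher. Of 1393 fragments typed as Other, 158 were lower and 216 higher, with a median log2 fold change of -0.07. With camera at a preset correlation of 0.01, these 7 lists were called lower and the 6 lists of the tiRNA-5, lysine, glycine and histidine fragments higher. The leucine call was lost without control replicate 1 (camera adjusted p = 0.163). The mitochondrial call was lost without control replicate 2 (camera adjusted p = 0.159) or experimental replicate 2 (0.286). The glycine, histidine and Other calls were lost without control replicate 2 (camera adjusted p = 0.264, 0.146 and 0.18), control replicate 3 (0.324, 0.0712 and 0.177) or experimental replicate 2 (0.298, 0.214 and 0.38). None of the 13 was called with an estimated correlation, where the adjusted p lay between 0.641 and 0.889, or with fry. In the remaining families and types camera made no call. Of 567 tRF-5c, 72 were higher and 2 lower, of 166 glutamic acid fragments 34 were higher and 5 lower, and of 35 valine fragments 12 were higher and 1 lower. Each of the other lists without a call had at most 4 fragments higher and at most 2 lower.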

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

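All tests of the mitochondrial mismatches, the mean 3' ends of glycine and glutamic acid fragments, leaving out libraries for the length of other reads, and the counts over other splits for fragments and anticodons were chosen after the result was seen. The tests of the whole CCA end and of the length of other reads were written down before theirs.

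The mismatch notes of the table, which the planned comparisons used only to keep exact matches, hold a signal that separates the groups. Reads were pooled over 7 mitochondrial positions in 6 tRNAs. Those without the base of the control libraries made up 94.79%, 80.84% and 88.0% in experimental replicates 1, 2 and 3. In a control library they made up at most 0.68%. The positions, counted from the mature 5' end, are G5A in mt-His, A16G in mt-Pro, C53G in mt-Tyr, A16T and T51C in mt-Cys, G42A in mt-Asp, and T74C beyond the 3' end of mt-Val. The base of the control libraries differs from the reference there. Single positions differed widely in the experimental libraries. The control base took 26.3%, 64.1% and 54.8% of the reads of replicates 1, 2 and 3 at A16G of mt-Pro. At T51C of mt-Cys, which had many more reads, it took 0.5%, 1.4% and 1.2%. The search left out 2 bases at each read end and positions with under 30 reads in a group, so further positions may exist. Among 3 nuclear positions, C101A beyond tRNA-His-GTG-1-7 stood at 98.3% to 100% in the control and 8.7% to 27.8% in the experimental libraries, on 18 to 90 reads per library. C49T in Leu-CAA stood at 55.6% to 75.0% and 0.0% to 6.9%, and T16C in Phe-GAA overlapped, at 55.6% to 100% in the control and 2.3% to 57.1% in the experimental libraries.

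Reads exchanged between libraries in both directions are argued against by the tables. Control-type reads in the experimental libraries, per such read in the control libraries, were at least 9.8 times the reverse ratio at each of the 7 positions, with the reverse reads counted as at least 3. Reads carried over from these control libraries alone are argued against too. The carried fraction implied by the positions of 1 experimental library differed at least 8.9-fold, whichever control library was taken as the source, and at most 4.03-fold where a control library was set against the others. A strain or donor variant against the reference remains a candidate explanation and cannot be told apart from the groups, since the control base reached at least 94.1% in every control library with 20 reads at a position and the labels name 1 strain for all samples. All 7 positions ranked the experimental libraries alike by their share of the control base, replicate 2 first and replicate 1 last. An admixture of control-type RNA with another make-up, which would give such an order, a wrong label and a biological difference of the experimental tissue stay open and untested.

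Last-base mismatches also differed. Those called A made up 33.86%, 31.63% and 31.97% of last-base mismatches in experimental replicates 1, 2 and 3, and at most 27.87% in the control libraries. Those called C made up 15.48%, 15.14% and 13.97%, and at most 7.36%. Those called G made up 32.95% in control replicate 2, and 1.67% and 1.69% in the other control libraries.

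The 3' ends of 5' fragments of Gly-GCC and Gly-CCC lay further 3' in the experimental libraries, by 0.652 nt on average. Tables argue against a general loss of bases at RNA 3' ends in the control libraries, since the share of 3' fragment reads with the whole CCA end differed by -14.03 percentage points, experimental minus control, where such a loss needs a higher share in the experimental libraries. A size selection of longer reads in the experimental libraries is not settled. Reads of other tRNAs were also longer there, by 3.14 nt (1.69 nt without experimental replicate 2), as such a selection would give. Their mean length also depends on which tRNAs make them up, and the Lys-CTT sum rose from 10400 to 72924 CPM. The length of other reads therefore cannot tell a size selection from a change in make-up. The ends on glutamic acid tRNAs shifted the opposite way, by -2.57 nt. A selection of longer reads would not give this for those tRNAs, but a selection of a range of lengths could give both shifts. Reads of 33 to 35 nt took 18.3 percentage points more of the reads in the experimental libraries. Glu-CTC 1 to 39 had a log2 fold change of -1.39 and Glu-CTC 1 to 33 of 1.36, neither called. The glutamic acid shift therefore cannot decide on a size selection. A change in cleavage with the experimental condition stays open and untested.

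Counts of calls over the 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split called 586 fragments and the highest other split 0 (1 of 10 splits as large). It called 0 anticodons, as did every other split (10 of 10). It called 13 lists, and the highest other split 19 (6 of 10 as large), so calls of lists at the preset correlation arise as often without the groups.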

How the results depend on the processing

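The added alternatives, chosen after the data were seen, were limma trend, an unpooled spread, subsets without mitochondrial, glycine or mismatch-separated sequences, mature tRNAs alone, classes by position with a tolerance of 2 nt, 5' fragments by position in the lists, and leaving out libraries for lengths and lists. Of 1079 alternative values over 72 results, 946 kept direction and side of the threshold or, for counts, stayed within a factor of 1.5. Read shares and read length were judged by direction alone, since their smallest p of 0.1 (exact permutation test) could not cross the threshold. Fragments called higher were 18.69% of those tested (416), and 10.11% (225) with library totals, 2.72% (2109) without a filter, 0.67% (15) with unpooled spread, 9.74% (101) for exact matches and 14.25% (197) without mitochondrial sequences. Fragments called lower were 7.64% (170), and 1.28% (993) without a filter, 0.36% (8) with unpooled spread, 8.78% (91) for exact matches and 7.74% (107) without mitochondrial sequences. Fewer fragments were tested for exact matches (1037) and without mitochondrial sequences (1382), which does not by itself lower a percent. For exact matches 52.6% of the calls were higher, against 71% in the main fit. The causes were not tested. Leaving out 1 library gave 6.96% to 21.21% higher and 4.14% to 8.99% lower. Anticodons called higher numbered 0, and 1 with library totals, with fragment-based factors and with mature tRNAs alone (Lys-CTT), 1 with sequences of 1 anticodon (Val-CAC), 2 with limma trend, and 0 to 2 with 1 library left out. Lists called fell from 6 higher and 7 lower to 0 and 0 with an estimated correlation and with fry, and with 1 library left out 4 to 8 were higher and 6 to 10 lower, with at least 4 of the 6 and 5 of the 7 kept. The labels do not say whether equal replicate numbers pair samples, and the correlations of their deviations (-0.31, -0.057 and 0.136) cannot settle it. With the replicate block 367 fragments were higher and 141 lower, and 0 anticodons, 6 lists higher and 7 lower were called. DESeq2 was not run. Depth limits rare fragments most in the control libraries.

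Values that turned in direction, none of them called, are log2 fold changes or percentage points. With at least 10 counts in every library of a group and without mitochondrial sequences, Gly-GCC 1 to 31 of chromosome 13 stood at -0.20 and -0.28, Gly-CCC and Gly-GCC 1 to 28 at -0.16 and -0.24, and the His-GTG fragment with C0G at -0.089 and -0.17. With no filter, the Arg-ACG trailer fragment stood at 0.42, Pro 17 to 30 at 0.11 and Tyr-GTA 60 to 76 at 0.011, and without glycine the Arg-ACG fragment stood at 0.31. Gly-CCC sums stood at 1.24 with sequences of 1 anticodon and 0.071 with mature tRNAs, and Thr-AGT at -0.455 there. The tRF-1 share stood at -0.003 points without the 5 most abundant sequences and at -1.27, -1.26 and -1.26 by position with tolerances of 0, 4 and 2 nt. The Other share stood at -8.69 without the 5 most abundant sequences. By distinct fragments tRF-5a stood at 0.04 and tRF-5b at 0.09. With 1 library left out, the ranges were -0.72 to 1.10 for Gly-GCC 1 to 31, -0.68 to 1.54 for Gly 1 to 28, -0.60 to 0.49 for Arg-ACG, -0.71 to 1.13 for His-GTG, -1.01 to 0.28 for Met-CAT, -0.99 to 0.016 for Pro, -1.19 to 0.62 for Tyr-GTA, -0.28 to 0.34 for Gly-CCC sums, -0.154 to 10.4 points for Other and -0.242 to 0.08 points for tRF-5b. The cause was not tested.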

Other observations

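Among the most abundant members of further lists, 2 were called and the rest named here were not. Asp-GTC 37 to 69 stood at 972 ± 1349 CPM in the control and 131 ± 48.9 CPM in the experimental libraries (limma voom adjusted p = 0.096). Gln-CTG 59 to 75 stood at 1225 ± 1505 and 170 ± 54.8 CPM (limma voom adjusted p = 0.0786), and Leu-AAG and Leu-TAG 68 to 85 at 1204 ± 953 and 317 ± 112 CPM (limma voom adjusted p = 0.14). With at least 10 counts in every library of a group all 3 were called lower (limma voom adjusted p = 0.0245, 0.019 and 0.0385). Without control replicate 1 their log2 fold changes went from -1.88, -1.97 and -1.69 to -0.588, -0.837 and -1.04. Asp-GTC was called without control replicate 3 (adjusted p = 0.0489) and Gln-CTG without control replicate 2 (adjusted p = 0.0309). A fragment beyond the 3' end of the initiator tRNA iMet-CAT, positions 73 to 88, rose from 14.4 ± 4.92 to 86.0 ± 38.9 CPM (limma voom adjusted p = 0.0479), and Thr-TGT 60 to 76 fell from 223.4 ± 240.5 to 33.5 ± 22.1 CPM (limma voom adjusted p = 0.0485). Both calls were lost under most alternatives, control replicate 3 left out among them, where the adjusted p were 0.223 and 0.0728. Control replicate 1 held 496 CPM of the Thr-TGT fragment and the other control libraries 40.3 and 134 CPM, and without it the log2 fold change went from -2.23 to -1.28 (adjusted p = 0.327).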
